A study of Homo sapiens with 2 samples.

How the data were processed

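RNA of 2 samples of the human cell line HCT116 was sequenced, 1 labelled GART-OE and 1 labelled wildtype, and the groups were taken from the sample titles and genotype labels. Per the labels' protocols, total RNA was extracted with Trizol, poly(A) RNA was isolated on oligo-dT beads and fragmented, and paired-end libraries were sequenced on an Illumina NovaSeq instrument. The same protocol text mentions an adipose type, and the source label and series title name multiple myeloma, while the cell line label and both titles name HCT116. The labels do not settle this conflict, and the text uses the cell line label.

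A single deposited table compared the 2 samples. The expression values are FPKM, per the file headers, written by the authors with 2 decimals. The table also holds the authors' deposited fold change (a ratio of GART-OE over wildtype), its log2, a p-value and a q-value per gene, per the file headers. Per the submitters' processing notes, HISAT2 2.0, StringTie 1.3.0 and Bowtie 0.12.2 were used, with no role stated for any of them. The same notes name the mouse build mm8, whereas the gene identifiers in the table are human Ensembl identifiers, so the build to which reads were aligned is not settled. The annotation release, the use of strand and the model behind the deposited p-values are not given in the sources used here. Of the gene identifiers, 58394 (96.3%) matched GENCODE 29, from which coordinates (GRCh38), transcript lengths, GC content, gene overlaps and host genes were taken.

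The table holds no counts. In genes with 1 annotated transcript of 250 to 900 nucleotides, FPKM multiplied by length peaked at 58.5 in GART-OE and at 50.4 in wildtype. A second peak lay at 1.97 and 2.01 times the first. Both peaks were sought only within set windows, the second around the expected multiple of the first, so its place is a weak check. Taking the first peak as 1 fragment gives about 17100000 and 19800000 fragments. Only 32.6% and 29.9% of the low values lay within 10% of a whole multiple, so whole reads were not recovered and no count test was run. At these depths 1 fragment in a transcript of 1 kilobase is worth 0.0585 and 0.0504 FPKM, and the median expressed gene had about 180 and 395 fragments. FPKM of all genes summed to 338817 and 326522. A total of 33408 genes are listed at 0 in both libraries.

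The log2 ratio was computed as log2((GART-OE + 1) / (wildtype + 1)) from FPKM, which understates differences of low genes. Genes with a mean of at least 1 FPKM over both libraries were taken as expressed, and a difference of 2-fold on that scale was counted. The median log2 ratio of expressed genes, -0.60, was subtracted where a ratio is given relative to the median gene. With 1 library per group no test, standard error or p-value was made from genes. For 37 gene lists, the median log2 ratio of the expressed members was placed among the medians of 10000 random lists of the same size, drawn from expressed genes in 20 bins of mean FPKM. Lists with fewer than 5 expressed members were not placed. As a further description, lists were placed among random lists of protein-coding genes matched on mean FPKM, transcript length and GC content, a matching written before its result was seen for the cell cycle and MAPK lists and run on all others afterwards. A percentile describes these 2 libraries and is not a p-value. Intervals of medians in the closing part are the middle 95% of 10000 bootstrap resamples over genes and describe the spread between genes only.

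The lists, the 2-fold limit, the filter, the rule for named genes and most alternatives were fixed before the data were examined. The rule named GART and all members of the de novo purine list. It added the 10 genes with the largest and the 10 with the smallest log2 ratio among genes with a protein-coding transcript, a gene symbol that is not a clone, noncoding or pseudogene name, and at least 5 FPKM in the higher library. From each pathway, complex or locus list it allowed up to 4 members with a log2 ratio of at least 1 in size, or else the highest and the lowest. From each cell type or RNA quality list it took the 3 with the highest mean, and of these the text names some. Members named because a count was 5 or fewer, and not by the rule, were chosen after their values were seen. Values of some genes that the rule selects are not reported here. The members so named were TMEM50B, SLC5A3, NME1, NME2, NT5E, GDA, MTHFD1, CCNE1, CDC20, SOX9, BAMBI, EPHB3, AXIN2, DKK1, SPRED1, XPC, SLC1A5, HSPB1, ACTB, B2M, TUBB and TBP. Transcripts with at least 97% identity to another gene over at least 30% of their length were found with BLAST 2.17.0, and the shared part is named for some of these genes. Besides those the text names, SLC25A32, RNF43 and SRCAP share most of their transcripts with overlapping genes, NME2 overlaps NME1 read-through transcripts, and DCK overlaps MOB1B. RPPH1 is shared in full with another annotated gene, and RPS2 and TUBB share over 50% of their transcripts with pseudogenes. Of 214 genes named or selected by the rule, 72 have exons that overlap a gene on the opposite strand, among them TYMS, FEN1, PLK1, GINS2, DNAJB1, SHMT1, TCF7, SLC19A1, XPC, PES1, MRTO4, RUVBL1 and DDIT3. The use of strand is not stated, so reads of these genes may be shared.

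The steps were tested on simulated data. Poisson fragment counts were drawn for 11568 genes at the estimated depths, with 200 genes changed. Of the genes simulated at 4-fold, 47 of 50 passed 2-fold, as did 44 of 50 at 3-fold and 0 of 50 at 1.5-fold. Of 11368 unchanged genes, 37 (0.325%) passed from counting error alone, which leaves out all spread between cultures. Of 100 random lists of 15 genes, 8 lay outside the middle 95% of random lists, and 82 of 100 lists shifted by 1 log2 unit lay above it. The alternatives were pseudocounts of 0.1 and 5, no filter or a mean of at least 10 FPKM, centring on the median gene, rescaling by a trimmed mean (30% of ratios and 5% of levels trimmed at each end) and leaving out ribosomal protein and mitochondrially encoded genes. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.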

Results

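Gene expression was measured by poly(A)-selected RNA sequencing in 2 libraries of HCT116, a human colorectal carcinoma cell line. The first library came from cells labelled as overexpressing GART (GART-OE) and the second from wildtype cells, so each group held 1 sample. GART encodes the trifunctional enzyme that catalyses several steps of de novo purine synthesis. The deposited table gave an FPKM value (fragments normalised for transcript length and library size) for 60612 genes in each library, with no counts. The spacing of the lowest values gave a rough estimate of the depth, about 17100000 fragments for GART-OE and 19800000 for wildtype. Of these genes, 11606 had a mean of at least 1 FPKM and were taken as expressed, 9983 of them with a protein-coding transcript. With 1 library per group, none of the differences has a replicate check, and no p-value was computed. The words higher and lower describe these 2 libraries only.

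The first question was whether GART differed as the labels state. GART (ENSG00000159131) was listed at 919.74 FPKM in GART-OE and at 23.54 FPKM in wildtype, a 39.1-fold difference. On the scale of log2(FPKM + 1), the difference was 5.23, or 5.83 relative to the median expressed gene. The gene lies on the minus strand of chromosome 21 from 33503931 to 33543491 (GRCh38, GENCODE 29), and its exons overlap those of SON on the opposite strand. SON was lower in GART-OE, at 5.81 FPKM against 20.24 FPKM. The table does not separate transcripts of the endogenous gene from those of an introduced copy. Among 12 expressed genes near GART on chromosome 21, the median log2 ratio was -0.12 relative to the median gene, at percentile 39.9 of random lists. Of these, SON and the interferon receptor gene IFNAR1, with 0.45 FPKM against 4.79 FPKM, were at least 2-fold lower relative to that gene, and TMEM50B and SLC5A3 were at least 2-fold higher.

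The second question was which other genes differed by at least 2-fold. With GART left out, the genes named first are the 10 with the highest log2 ratios among protein-coding genes with at least 5 FPKM in the higher library. Some noncoding RNAs had higher ratios than several of them. The phosphatase gene DUSP1 (chromosome 5, 172768090 to 172771195) had 210.81 FPKM against 6.71 FPKM. The stress gene GADD45B had 134.3 FPKM against 4.11 FPKM, the clock gene PER1 158.96 FPKM against 5.34 FPKM, and MAFF, a small MAF transcription factor gene, 75.46 FPKM against 2.31 FPKM. NR1D1, which encodes a nuclear receptor of the clock, had 253.51 FPKM against 11.53 FPKM, and its exons overlap THRA on the opposite strand.

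The remaining members of the 10 genes with the largest log2 ratios share sequence with near-identical copies or belong to the histone families. HSPA1A, which encodes an inducible HSP70 chaperone, had the highest log2 ratio of them, 7.20, but its transcript is nearly identical to that of HSPA1B. Summed over HSPA1A and HSPA1B, the FPKM was 1047.3 in GART-OE and 197.49 in wildtype, a 5.30-fold difference. The histone genes H2AC18 and H2AC19 are copies of each other, and their sum was 374.02 FPKM against 3.11 FPKM. H2BC21 had 45.54 FPKM against 0.42 FPKM. The keratin-associated gene KRTAP2-3, which shares sequence with KRTAP2-4 and KRTAP2-1, had 98.54 FPKM against 0.97 FPKM.

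Among the genes lower in GART-OE, PSME3, which encodes a proteasome activator subunit, had 2.43 FPKM against 48.44 FPKM, and its exons overlap BECN1 on the opposite strand. CENPB, which encodes a centromere protein, had 2.01 FPKM against 36.93 FPKM. HPS6 had 0.27 FPKM against 18.3 FPKM, and the nuclear receptor coactivator gene NCOA5 had 0.61 FPKM against 21.51 FPKM. CYP24A1, which encodes the vitamin D 24-hydroxylase, had 0.7 FPKM against 22.44 FPKM, and INTS5, which encodes an Integrator subunit, had 0.56 FPKM against 15.95 FPKM. TOMM6, a mitochondrial import gene, had the lowest log2 ratio of the 10, -4.31, but an overlapping gene contains its whole transcript. TNFRSF6B overlaps a read-through gene, and ARPIN-AP3S2 is itself a read-through gene that overlaps ARPIN and AP3S2. TUBB2B shares most of its transcript with TUBB2A, so the values of all these genes are uncertain too. Their FPKM values were 0.16 against 17.75 for TNFRSF6B, 0.01 against 10.78 for ARPIN-AP3S2 and 0.06 against 11.61 for TUBB2B.

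In all, 1075 expressed genes (9.26%) were at least 2-fold higher in GART-OE and 3840 (33.1%) were at least 2-fold lower. This split depended on the scale, because the median expressed gene had a log2 ratio of -0.60, which is 1.51-fold higher in wildtype. Relative to that median gene, 2143 genes were at least 2-fold higher and 1461 at least 2-fold lower. Thus 59.5% of the genes past 2-fold were higher, against 21.9% on the deposited scale. Deposited scale here means the log2 ratio of FPKM + 1 before this centring, not the authors' own log2 fold change. Log2 ratios and member counts of gene groups are therefore given relative to the median gene in what follows. The ratio on the deposited scale is named where its direction differs. On the deposited scale, 3603 of the lower genes but 574 of the higher genes had a protein-coding transcript.

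**Figure D1:**
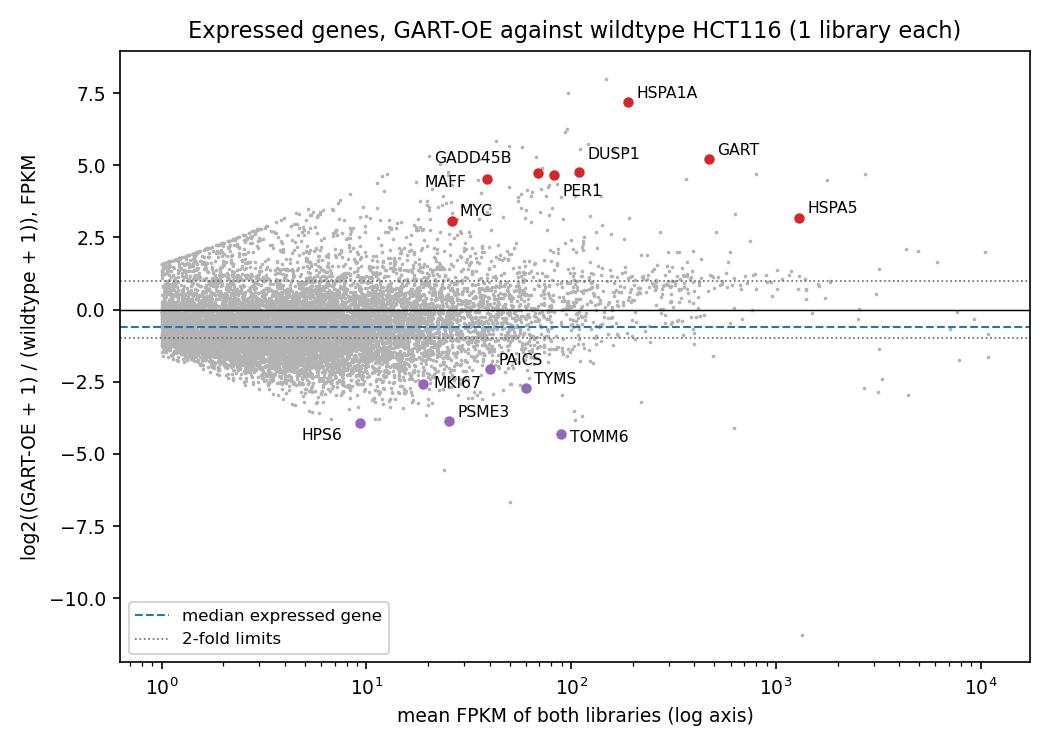
Log2 ratio of GART-OE over wildtype on the deposited scale, log2(FPKM + 1), against the mean FPKM of both libraries on a log axis, 1 point per expressed gene. Most points lie below 0, the dashed line marks the median gene at -0.60, and named genes are coloured red where higher and purple where lower in GART-OE on both scales.

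The third question was how defined gene groups differed, first those of nucleotide synthesis. Apart from GART, 5 of the 12 expressed genes of de novo purine synthesis were at least 2-fold lower in GART-OE and 1 was higher. PAICS, which catalyses the steps after AIR formation, had 14.89 FPKM against 65.19 FPKM, PFAS 1.53 FPKM against 8.75 FPKM, ADSL 2.28 FPKM against 9.55 FPKM and ATIC 12.26 FPKM against 35.74 FPKM. GMPS and ADSS2, of the GMP and AMP branches, had log2 ratios of -1.18 and -1.25. PRPS1 and PRPS2, which make the precursor PRPP, and IMPDH1 had ratios of -0.31, -0.25 and -0.03. PPAT, the committed enzyme, had a ratio of 0.34, although its ratio on the deposited scale was -0.26. IMPDH2 and ADSS1 had ratios of 0.94 and 1.67. Over all 13 expressed genes of the list, 5 were at least 2-fold lower, 2 (GART and ADSS1) were at least 2-fold higher, and the median log2 ratio was -0.31, at percentile 9.97 of random lists and 22.2 when matched on length and GC content as well. Without GART, a choice made after the values were seen, the median was -0.59, at percentile 2.25.

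Genes of pyrimidine and deoxynucleotide synthesis stood below random lists, with a median of -0.70 at percentile 0.13. Of the 16 expressed members, 5 were at least 2-fold lower and 1, NME2, was higher, with 192.92 FPKM against 126.12 FPKM. Thymidylate synthase (TYMS) had 15.29 FPKM against 105.22 FPKM, UMPS 0.73 FPKM against 7.83 FPKM, CTPS1 1.24 FPKM against 7.88 FPKM and DTYMK 6.5 FPKM against 28.12 FPKM, and NME1 was lower too. The KEGG term Pyrimidine metabolism, with 5 of 43 genes higher and 8 lower, lay within the random range at percentile 9.84. Folate one-carbon genes had a median of -0.52 at percentile 4.35, and 5 of 15 were at least 2-fold lower. Among these, the mitochondrial folate carrier gene SLC25A32 had 1.26 FPKM against 9.24 FPKM and SHMT1 1.73 FPKM against 9.98 FPKM, beside MTHFD1 and the folate transporter gene SLC19A1. Although this list stayed within the middle 95% of random lists, the KEGG terms One carbon pool by folate, with a median of -0.78 over 13 genes at percentile 0.27, and Antifolate resistance, at percentile 0.42, lay below it. Purine salvage genes went both ways, with 3 of 13 higher (PNP, NT5E and GDA) and 1 lower (DCK). Their median was 0.22 (-0.38 on the deposited scale), at percentile 77.3. Purine nucleoside phosphorylase (PNP) had 73.04 FPKM against 20.36 FPKM, while the deoxycytidine kinase gene DCK had 2.83 FPKM against 11.6 FPKM and MTAP 1.05 FPKM against 4.95 FPKM.

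**Figure D2:**
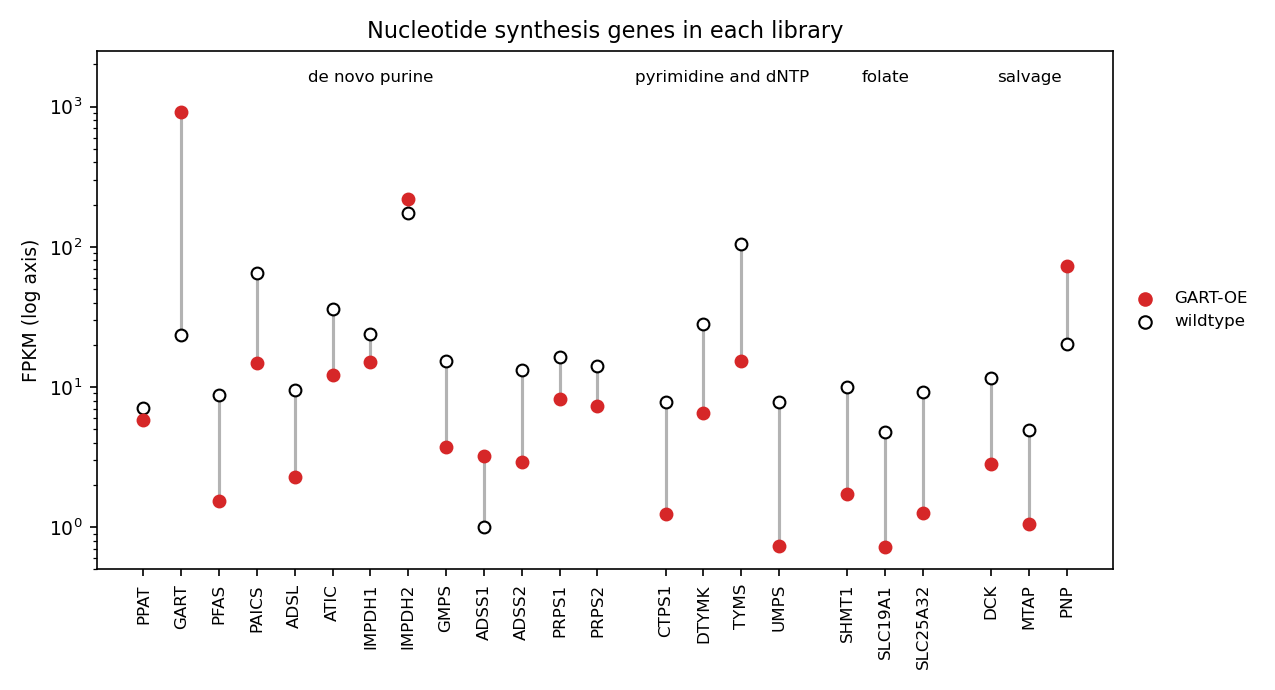
FPKM of nucleotide synthesis genes on a log axis, with 1 red point for the GART-OE library and 1 open point for the wildtype library per gene. GART had 919.74 FPKM against 23.54 FPKM, while PAICS, with 14.89 FPKM against 65.19 FPKM, and TYMS, with 15.29 FPKM against 105.22 FPKM, were lower in GART-OE.

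Cell cycle and DNA repair genes were lower in GART-OE. Of 20 S phase and replication genes, 15 were at least 2-fold lower, with a median of -1.22, and 1, the cyclin gene CCNE1, was higher, with 32.87 FPKM against 19.35 FPKM. FEN1, the flap endonuclease gene, had 14.94 FPKM against 100.86 FPKM, the helicase genes MCM4 and MCM6 had 8.45 FPKM against 48.71 FPKM and 7.68 FPKM against 43.16 FPKM, and GINS2 had 2.73 FPKM against 23.53 FPKM. Of 19 mitosis genes, 8 were lower, with a median of -0.96, and 1, the checkpoint gene CDC20, was higher, with 317.7 FPKM against 195.61 FPKM. The mitotic kinase genes AURKA and PLK1 had 2.67 FPKM against 31.24 FPKM and 5.76 FPKM against 35.11 FPKM, and the proliferation marker MKI67 had 4.74 FPKM against 32.93 FPKM. Of 14 mismatch and double-strand repair genes, 8 were lower and none was higher by 2-fold, with a median of -1.06, and RBBP8, which encodes a DNA end resection factor, had 1.6 FPKM against 9.88 FPKM. All 10000 random lists had medians above that of each of these 3 lists.

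MYC target genes were lower as well, while MYC itself was higher. Of 20 targets, 7 were at least 2-fold lower and none was higher, with a median of -0.75, below all 10000 random lists. The ribosome assembly genes RRS1, MRTO4 and PES1 had 3.44 FPKM against 36.69 FPKM, 5.58 FPKM against 50.48 FPKM and 11.18 FPKM against 44.15 FPKM. MYC (chromosome 8, 127735434 to 127741434), a member of the Wnt target list, had 47.38 FPKM against 4.71 FPKM. The other Wnt targets went both ways, with 4 of 14 list members higher (MYC, SOX9, BAMBI and EPHB3) and 5 lower (RNF43, ZNRF3, TCF7, AXIN2 and DKK1). The Wnt list had a median of -0.29 at percentile 12.9, and RNF43 had 3.41 FPKM against 26.33 FPKM. RUVBL1, an ATPase of chromatin remodeling complexes, had 4.58 FPKM against 28.88 FPKM, and its list had a median of -0.50 at percentile 7.01, with 3 of 14 lower (RUVBL1, SRCAP and ACTR8).

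The fixed lists of MAPK feedback and AP-1, cholesterol synthesis and hypoxia genes stood above random lists, whereas most related KEGG terms in the table did not. Of 17 MAPK feedback and AP-1 genes, 9 were at least 2-fold higher and 1, SPRED1, was lower, with a median of 1.12 at percentile 97.9. JUN had 120.04 FPKM against 6.94 FPKM, EGR1 197.9 FPKM against 33.39 FPKM and DUSP5 345.94 FPKM against 37.56 FPKM. Cholesterol synthesis genes had 14 of 20 higher and none lower by 2-fold, with a median of 1.62, above all 10000 random lists. INSIG1, a sterol sensor partner, had 69.07 FPKM against 3.28 FPKM, the sterol oxidase gene MSMO1 141.56 FPKM against 8.29 FPKM, MVD 114.36 FPKM against 12.97 FPKM and HMGCS1 31.88 FPKM against 3.84 FPKM. Genes of the hypoxia and glycolysis list had 8 of 16 higher and none lower by 2-fold, with a median of 1.28 at percentile 99.9. The aldolase gene ALDOC had 142.28 FPKM against 13.86 FPKM, and NDRG1 110.96 FPKM against 9.16 FPKM. Among KEGG terms, MAPK signaling lay at percentile 73.3, HIF-1 signaling at 82.1, Steroid biosynthesis at 85.4 and Terpenoid backbone biosynthesis at 8.73. Glycolysis / Gluconeogenesis went the other way, with a median of -0.18 over 42 genes at percentile 2.16, and Cholesterol metabolism lay above the range at 98.5.

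Interferon response genes had 7 of 10 expressed members at least 2-fold higher and none lower, with a median of 1.82 at a percentile of 99.99. Before centring, this list had a median of 0.03 over 19 members without the filter on low values, against 1.22 with it. Without the filter it lay within the random range at percentile 93.7. The ubiquitin-like modifier gene ISG15 had 472.78 FPKM against 72.24 FPKM and IFI6 50.58 FPKM against 6.85 FPKM. NF-kB and inflammatory genes had 7 of 8 higher and 1 lower, with a median of 1.68, above all 10000 random lists. Before centring, the NF-kB list median of 1.08 fell to 0.49 over 15 members without the filter and to 0.44 with a pseudocount of 5. Both values were still above all random lists. The KEGG term NF-kappa B signaling, with 9 of 53 genes higher and 7 lower, lay at percentile 72.0. The inhibitor gene NFKBIA had 26.75 FPKM against 7.91 FPKM, CXCL8 4.92 FPKM against 0.18 FPKM and ICAM1 0.51 FPKM against 4.42 FPKM. Restricted to genes with a mean of at least 10 FPKM, fewer than 5 members of the interferon, NF-kB, histone and repair lists remained, and these lists could not be placed.

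Stress lists stayed within the range of random lists matched on mean FPKM, and single members differed strongly. Of 18 p53 targets, 6 were higher and 1, the repair gene XPC, was lower, with a median of 0.74 at percentile 97.4. PLK3 had 107.99 FPKM against 5.82 FPKM, GADD45A 263.33 FPKM against 16.28 FPKM and BBC3 37.55 FPKM against 3.39 FPKM. The p53 targets MDM2 and BAX, chosen after their values were seen, stayed within 2-fold of the median gene. They had 3.51 FPKM against 6.49 FPKM and 16.31 FPKM against 21.31 FPKM. The p53 list stood above the middle 95% of random lists with a pseudocount of 5 and with a mean of at least 10 FPKM (percentile 99.6). It also did so when matched on length and GC content as well (percentile 98.7). Without the filter it lay within the range at percentile 94.6, as did the KEGG term p53 signaling pathway, with 60 genes, at 84.0. The serine synthesis and ATF4 target list had a median of 0.45 (-0.15 on the deposited scale) at percentile 72.7, with 7 of 20 higher and 2 lower (PSPH and SLC1A5). Its members DDIT3 and ATF3, transcription factor genes of the stress response, had 116.15 FPKM against 5.55 FPKM and 44.31 FPKM against 2.71 FPKM. Endoplasmic reticulum chaperones had a median of 0.84 at percentile 87.3, or 98.0 when matched on length and GC content as well, with 7 of 14 higher. On the deposited scale, 2 were at least 2-fold higher and 1, XBP1, was lower, with 7.97 FPKM against 19.16 FPKM. HSPA5, the main chaperone of that compartment, had 2334.08 FPKM against 255.14 FPKM. Heat shock genes had a median of 0.62 at percentile 23.6, with 5 of 11 higher (HSPA1A, HSPA1B, HSPA8, HSPB1 and DNAJB1), and DNAJB1 had 345.85 FPKM against 92.67 FPKM. The other heat shock members stayed within 2-fold of the median gene, and on the deposited scale 4 members were higher and 1 was lower.

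The other pathway lists also stayed within that range, although apoptosis regulators left it under 2 other settings. Apoptosis regulators had a median of 0.60 (0.00 on the deposited scale) at percentile 94.3. They lay at percentile 98.3 with a mean of at least 10 FPKM and at 98.5 when matched on length and GC content as well, and CASP8 had 0.32 FPKM against 3.53 FPKM. Mesenchymal genes had a median of 0.67 over 7 expressed members at percentile 91.6, and SNAI1 had 51.01 FPKM against 9.44 FPKM. Epithelial junction genes had a median of 0.33 (-0.27 on the deposited scale) at percentile 55.9, with CLDN4 at 128.36 FPKM against 29.68 FPKM and DSP at 6.6 FPKM against 31.71 FPKM. NRF2 targets had a median of -0.28 at percentile 6.87, and the transporter gene ABCC2 had 2.67 FPKM against 26.14 FPKM. Nuclear oxidative phosphorylation genes had a median of 0.08 (-0.52 on the deposited scale) at percentile 9.56, with none of 18 past 2-fold, while the KEGG term of that name lay at percentile 1.85. Of the 29 lists that could be placed, 6 fell below the middle 95% of random lists and 6 above it, or 6 and 10 when matched on length and GC content as well.

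**Figure D3:**
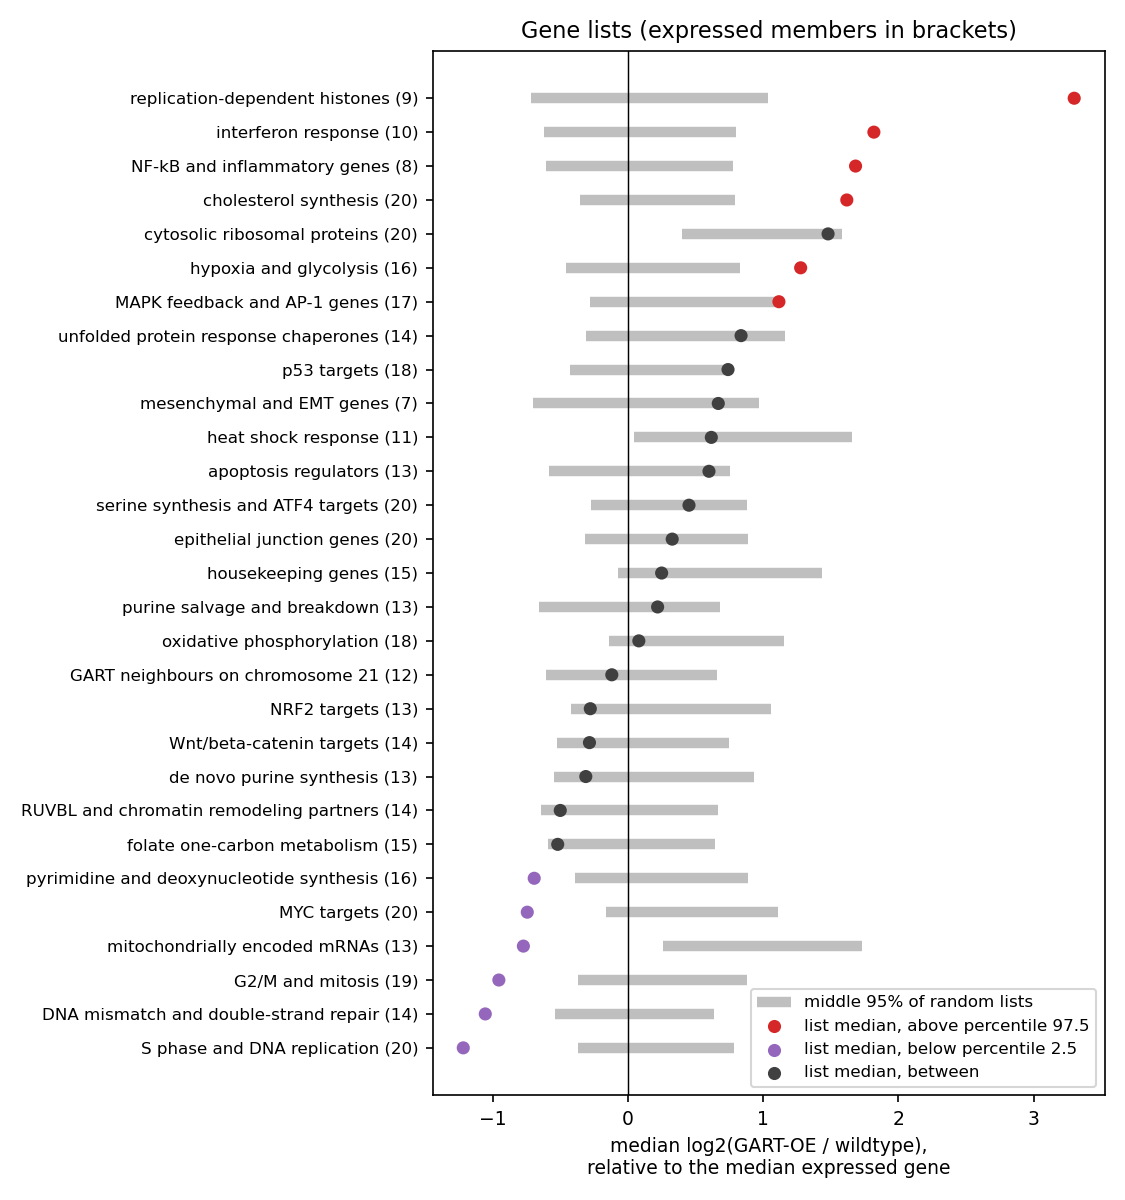
Median log2 ratio of 29 gene lists relative to the median expressed gene (points), with the middle 95% of medians of 10000 random lists matched on mean FPKM (grey bars) and the number of expressed members in brackets. Among lists with at least 5 expressed members, the ones drawn, S phase genes are lowest at -1.22 and replication-dependent histones highest at 3.30. The order does not depend on the median shift, and lists near 0 have the opposite sign on the deposited scale where the text says so.

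Lists of cell types and of RNA quality were described in both libraries, because the source label names multiple myeloma cells while the cell line label names HCT116. Of 17 plasma cell and myeloma markers, only SDC1, with 20.55 FPKM against 25.19 FPKM, and XBP1, with 7.97 FPKM against 19.16 FPKM, were expressed. Of 17 intestinal epithelium markers, 3 were expressed and each was lower in GART-OE on both scales. Among them were the intestinal transcription factor gene CDX2, with 0.35 FPKM against 6.95 FPKM, and the carbonic anhydrase gene CA2, with 4.9 FPKM against 20.41 FPKM. No B cell, T and NK cell or endothelial marker was expressed. CD68 was the 1 expressed myeloid marker, with 18.76 FPKM against 1.07 FPKM, but an overlapping read-through gene shares most of its transcript. Of the fibroblast markers, COL1A1 had 4.99 FPKM against 2.3 FPKM and ACTA2 2.09 FPKM against 2.28 FPKM. Of the adipocyte markers, CFD had 21.59 FPKM against 21.06 FPKM and PPARG 6.59 FPKM against 19.84 FPKM.

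Replication-dependent histone mRNAs, which mostly end without a poly(A) tail, were higher in GART-OE in 9 of 9 expressed members, with a median of 3.30 at a percentile of 99.99. H1-2 had 167.5 FPKM against 10.21 FPKM. Cytosolic ribosomal protein genes were at least 2-fold higher in 20 of 20 members, or in 6 of 20 on the deposited scale. Their median was 1.48 at percentile 93.0, and it lay above all 10000 random lists when matched on length and GC content as well. On the deposited scale the median was 0.88, against 0.48 for random lists of like mean FPKM. Genes at this level thus tended to stand above the median gene too. RPS2 had 2419.43 FPKM against 1243.36 FPKM. Mitochondrially encoded mRNAs were at least 2-fold lower in 6 of 13 members, with a median of -0.78, below all 10000 random lists, and MT-CO2, whose transcript is shared with a nuclear pseudogene, had 5297.93 FPKM against 16524.7 FPKM. Housekeeping genes had a median of 0.25 (-0.35 on the deposited scale) at percentile 12.3, with 5 of 15 higher (among them EEF1A1, B2M, ACTB and GAPDH) and 2 lower (TUBB and TBP). EEF1A1 had 4615.76 FPKM against 1727.54 FPKM and GAPDH 3646.3 FPKM against 2532.54 FPKM. The differences in histone, ribosomal protein and mitochondrial transcripts separate the same 2 libraries as every gene group above.

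The authors' deposited table marks 991 genes as higher and 1865 as lower in GART-OE. Every gene marked in the authors' deposited table has a p-value of at most 0.05 and a log2 fold change of at least 1 in size, as written with 2 decimals. Of the marked genes, 886 have a q-value above 0.05 in the authors' deposited table, the largest being 0.17, and 356 have a mean below 1 FPKM. The authors' deposited table gives GART a fold change of 39.07. Of the genes that the authors' deposited table marks as lower, 36 lay above the median gene in the ratios computed here. For a gene at least 2-fold lower this can happen only at low FPKM, where the added 1 FPKM shrinks the ratio. None of the genes marked as higher lay below the median gene, and none could, because the ratio of that gene is itself below 0. With 1 library per group, these p-values contain no spread between replicates, and the model behind them is not given in the sources used here.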

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

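The restriction to protein-coding genes and the matching of random lists on length and GC content were chosen after the data were seen. The counts of genes past 2-fold, 1075 higher and 3840 lower, moved by over 1.5 times under 4 planned settings. A pseudocount of 5 gave 549 higher and 1196 lower, and a mean of at least 10 FPKM gave 464 and 838. The first shrinks the ratios of low genes, and the second leaves 3253 of the 11606 expressed genes. Centring on the median gene gave 2143 higher and 1461 lower, and rescaling by a trimmed mean gave 2097 and 2032. The share of higher genes was thus 59.5% and 50.8%, against 21.9% on the deposited scale. Both scalings only raise ratios, so all 1075 higher genes had to remain higher and the lower genes could only lose members. Of the 3840 lower genes, 1461 and 2032 remained lower. Protein-coding genes alone gave 574 higher, because 501 of the higher genes have no protein-coding transcript. A pseudocount of 0.1, no filter and leaving out ribosomal protein and mitochondrial genes kept both counts within 1.5 times. GART had a log2 ratio of 5.23, 5.83 after centring and 5.89 after trimmed-mean rescaling. The numbers of lists below and above random lists stayed between 5 and 7 on each side under the planned settings. Matched on mean FPKM, length and GC content, the same 6 lists lay below, and 10 lay above: the same 6 and those of p53 targets, endoplasmic reticulum chaperones, apoptosis regulators and ribosomal proteins. A pseudocount of 0.1 kept the same 12 lists, and a pseudocount of 5 added the p53 list. Centring moves lists and random lists alike, so it keeps every percentile by construction and is no check. Dropping the filter lost the interferon list (percentile 93.7) and added the folate and ribosomal protein lists, and a mean of at least 10 FPKM left 5 of 6 lower and 3 of 6 higher lists, and added the housekeeping list below and the p53 and apoptosis lists above. With a pseudocount of 5 the medians before centring of the repair, histone, interferon and NF-kB lists moved by over 1.5 times. They went from -1.66 to -0.76, 2.70 to 1.51, 1.22 to 0.48 and 1.08 to 0.44, and all 4 stayed outside the random range. None of the list medians outside the random range reversed sign under the settings run for them, and centring could not have reversed them. For the named genes at least 2-fold apart, only pseudocounts and shifts of less than 1 log2 unit were run. These cannot reverse the sign of such a gene, so they are no check of it. In the authors' deposited table, 366 higher and 226 lower genes had a fold change of at least 2 and a q-value below 0.01, against 991 and 1865 marked. The recomputation from a count column and the leaving out of columns were not run, because the table analysed here has 1 FPKM column per sample. Depth limits genes near 1 FPKM, and the missing replicates limit every difference.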

Other observations

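The genes and classes named in the first 2 paragraphs were chosen after their values were seen, as were the tests of FPKM scaling, of poly(A) selection and of heat stress. Several classes of small noncoding RNA were higher in GART-OE, while mitochondrial tRNAs were not. Of 114 expressed snoRNA genes, 100 were at least 2-fold higher relative to the median gene and 6 were lower, with a median log2 ratio of 2.65. Of 22 expressed mitochondrial tRNA genes, 4 were higher and 8 lower, with a median of -0.56. The signal recognition particle RNA genes RN7SL1 and RN7SL2, which are near-identical, had 162.63 FPKM against 6.98 FPKM and 238.54 FPKM against 3.44 FPKM. RN7SK had 70.37 FPKM against 0.92 FPKM, RMRP 40.43 FPKM against 1.27 FPKM, and the nuclear long noncoding RNA MALAT1 132.4 FPKM against 2.41 FPKM. The mitochondrial rRNAs MT-RNR1 and MT-RNR2 were higher too, with 7992.6 FPKM against 1933.86 FPKM for MT-RNR1. The mitochondrial mRNAs MT-ND2 and MT-CYB were lower, at 1002.35 FPKM against 7827.22 FPKM and 764.43 FPKM against 5549.29 FPKM. MT-ND4 and MT-ND6 differed less, with 8259.78 FPKM against 10287 FPKM and 2536.12 FPKM against 2526.16 FPKM. The transcripts of RN7SK, RMRP and MT-ND2 are shared in full with other annotated genes, for MT-ND2 a nuclear pseudogene, so their values depend on how shared reads were assigned.

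The KEGG annotation in the deposited table allowed 285 pathway terms of 10 to 200 expressed genes to be placed among random lists. With genes shared between terms, 23 of them fell below the middle 95% of these lists and 14 above it. By construction 2.5% of random lists lie on each side, and 8 of 100 simulated random lists lay outside. Part of these terms would therefore lie outside without any pattern. DNA replication was the term farthest below its random lists, with 18 of 34 genes at least 2-fold lower relative to the median gene and a median of -1.07. The proteasome term had a median of -0.47 over 41 genes at percentile 0.01, and ribosome biogenesis had a median of -0.52 over 71 genes at percentile 0.01. The ribosome term stood above all random lists, with 78 of 130 genes higher and a median of 1.23. The systemic lupus erythematosus term, which consists largely of histone genes, was farthest above, with 22 of 39 genes higher. Zinc finger genes with ZNF symbols had a median of -0.37 over 179 expressed genes, with 8 higher and 24 lower. MTATP6P1, a nuclear pseudogene near-identical to MT-ATP6, had 0.09 FPKM against 2675.01 FPKM, a value that depends on how reads shared with MT-ATP6 were assigned.

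Genes of the S phase, mitosis and repair lists were lower together in GART-OE. A change of scale alone would bring their pooled median to that of the other genes, but after centring it was -1.12 over 53 genes, with an interval of -1.26 to -0.96. Transcript length and GC content do not account for it either, since the pooled median lay at percentile 0, below all random lists of protein-coding genes matched on mean FPKM, length and GC. Cell density, time in culture and clonal differences stay open and were not tested, and no measurement of growth was analysed here. With 1 library per group, an effect of GART cannot be separated from the difference between these 2 cultures.

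Nuclear-encoded RNAs without a poly(A) tail (snoRNAs, 7SL, 7SK, RMRP, RPPH1 and 5.8S rRNA) were higher in GART-OE. Higher expression of the host genes was argued against for the snoRNAs, because 87 snoRNAs within a protein-coding host exceeded the host's log2 ratio by a median of 2.30 (interval 1.96 to 2.58). Less complete poly(A) selection in the GART-OE library stays open. The 9 genes of 7SL, 7SK, RMRP, RPPH1 and 5.8S rRNA had a median log2 ratio of 3.996 relative to the median gene (interval 3.29 to 5.81). They were picked after part of their values had been seen and include near-identical 7SL copies, so this value cannot support less complete selection. Replication-dependent histones, a list fixed beforehand whose mRNAs mostly lack the tail, were higher in 9 of 9 expressed members, with a median of 3.30. That list goes the way that less complete selection would, but it does not show the cause. Mitochondrial tRNAs, which also lack the tail and were not picked for the pattern, did not move with the others. Their median was -0.56 with an interval of -1.43 to 0.69. Mitochondrially encoded mRNAs had a median of -0.78, so the tRNA value cannot decide for or against poly(A) selection. The mitochondrial rRNAs MT-RNR1 and MT-RNR2 were higher, with log2 ratios of 2.64 and 2.58 relative to the median gene. Mitochondrial transcripts thus went both ways, and these rRNAs, picked after their values were seen, do not decide the question. Higher transcription of these RNAs was not tested.

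The MAPK feedback and AP-1 genes, with JUN, EGR1 and DUSP5, were higher in GART-OE. Transcript length and GC content were argued against, because the list lay at a percentile of 99.9 among random lists of protein-coding genes matched on mean FPKM, length and GC. Less complete poly(A) selection could raise some of them, and the list median relative to the median protein-coding gene, 1.21, had an interval of 0.21 to 2.997 over 17 members, which reached below the 0.3 required to exclude it. Heat stress at harvest stays open too: the heat shock list had a centred median of 0.62 with an interval of -0.07 to 2.37, too wide to decide. That list lay at percentile 23.6 of random lists matched on mean FPKM, and at 79.0 when matched on length and GC content as well. An effect of GART overexpression is a further open explanation, which 1 library per group cannot test.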
